A study of Nakaseomyces glabratus with 6 samples.

How the data were processed

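RNA sequencing libraries came from 3 biofilm and 3 planktonic samples of the *C. glabrata* isolate NCCPF-100037, which the labels describe as biological replicates. Per the labels' protocols, RNA was purified with a yeast kit and sequenced on an Illumina instrument in paired reads. No DNase step is named in the labels. Per the submitters' processing notes, FastQC, Trimmomatic, TopHat2 2.1.1, Bowtie2 and Cuffdiff were used. The genome build and whether reads were counted by strand are not given in the sources used here.

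Per the file headers, the deposited tables are Cuffdiff output with 1 FPKM value per locus and growth mode, made by the authors from the pooled replicates, a fragment density scaled to transcript length and library size. The authors' log2 fold change is that of biofilm over planktonic, and it differed from the log2 ratio of the deposited FPKM by at most 1.22e-05. The deposited test score, p-value and q-value are the authors' own. The q-value differed by at most 5.05e-07 from a Benjamini-Hochberg adjustment over the 4674 loci with a completed test, and the lowest p-value, 5e-05, was shared by 1751 loci. A further pair of deposited tables holds the 1237 higher and 1313 lower loci with gene names and gene ontology terms, and all 2550 called loci were found there with the same direction.

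The values hold no counts and no value per replicate. A count model per library, a gene set test on libraries, leaving out replicates and a replicate block, which had been planned before the data were examined, could not be run, and the authors' calls were used in their place. Depth per sample is unknown, so no counting interval is given. How the authors scaled the libraries to each other is not given in the sources used here. If FPKM is a plain share of all fragments, a few very abundant RNAs lower the FPKM of all other genes. For that reason alternative scalings were applied. The summed coding FPKM includes abundant ribosomal and glycolytic genes, so a fall in these genes alone also shifts it. Loci were named by the deposited gene names and by gene identifiers matched to the reference gene table ASM1011175v1, which gave an entry for 2307 of 2377 called loci with a gene. Uncalled loci carry only locus tags, which the reference gene table does not hold, so names and lists cover called loci alone, and a gene missing from the called loci may be unchanged, untested or unnamed. Of the loci, 489 join several genes, 288 have no gene and 2319 are printed with a span shared with other loci, up to 108 loci for one span. Starts are printed here counted from 1, since in 1615 of 1687 loci with a single gene the deposited span then equals the reference gene length.

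Gene groups were 29 lists fixed before the data were examined. Members were called loci with a single gene on its annotated strand (2089 genes), matched by symbol; names joined by a slash were split, and 2 genes whose symbol belongs to another gene and 1 ribosome assembly gene sharing an adhesin symbol were removed. For each of the 27 lists with at least 3 members, higher and lower members were compared with those among the other called genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over lists. This test is conditional on the authors' calls, and genes are not independent replicates. The planned count adjusted over the list alone could not be made, since uncalled members have no names. Beside it, the list's median was placed among 10000 random lists of called genes matched on mean FPKM. The code was run on simulated lists of 20 among the 2089 genes. Of 200 lists with 90% higher genes all were called higher, but each held the same counts, so that outcome was fixed in advance. Of 200 random lists 2.5% reached p under 0.05 by Fisher's exact test. That share is for genes drawn independently and does not cover lists of genes that change together. Gene ontology terms with at least 10 called genes were tested in the same way, 140 terms in all.

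Genes named in the text followed a rule fixed before the data were examined: the 12 largest changes in each direction among called genes above the lower quartile of mean FPKM (20.8), up to 4 members per list, taken by lowest q-value first in the direction that held more of its called members and then in the other, and a fixed set. With an even split the higher direction came first, which the rule had left open. Ties at the lowest q-value were broken by the size of the change, a choice made after the values were seen. The planned condition that every biofilm library lie on one side of every planktonic library could not be applied. Passed over for lack of a name or description were 2 genes at the higher end and 4 at the lower. Members outside the rule (such as ICL1, CAT8, SIP4, PYC2, POX1, PEX27, PDC6, GLK1, HXT3, HXT14, PWP5, YPS3, SIR3, YKU80, ISA1, MRS4, CTR1, CLB2, SGA1, HTB1 and HTA1) were chosen after their values were seen, and 2 genes are not reported here. Fold ratios are quotients of the deposited FPKM with no pseudocount; pseudocounts of 1 and 0.1 were tried. Fisher's exact test on calls, the split of joined names, the removed homonyms, the minimum of 10 genes per term, the scalings, the subsets of loci and the removed constants were chosen after the values were seen. Other alternatives were a q-value under 0.01, a 2-fold minimum, subsets of loci, scalings of FPKM, and removal of a constant from biofilm FPKM. Counts over the 8 alternatives leave out 3 scalings and the unsplit names, which changed the members or directions of at most 1 list. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.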

Results

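The transcriptome of *Candida glabrata* (*Nakaseomyces glabratus*), a yeast that colonises humans and causes opportunistic infection, was measured by RNA sequencing in the clinical isolate NCCPF-100037 in 2 modes of growth. The 3 biofilm samples were grown for 24 h at 37 °C in RPMI-1640 medium in polystyrene wells and rinsed before RNA extraction. The 3 planktonic samples were free-living cells. Their time in culture and temperature are not given in the labels, and no medium is stated here for them. Growth mode therefore cannot be separated from culture age, or from any difference in temperature or medium. Each locus had 1 FPKM value per growth mode in the authors' deposited table, pooled over the 3 replicates by the authors, together with their fold change and q-value. Errors between replicates, read counts and depth are therefore unknown here. Replicate spread enters only through the authors' test, whose score, p-value and q-value do not give that spread directly. The table held 4895 loci, of which 4674 had been tested.

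The comparison asked which genes differ in transcript level between the sessile and the free-living form of the isolate. In biofilm, transcripts of gluconeogenesis, the glyoxylate cycle, fatty acid oxidation, autophagy and the proteasome were higher. Transcripts of ribosomal proteins and ribosome assembly factors were lower, although 15 of 58 assembly factors and 11 of 28 mitochondrial ribosome genes would be higher after scaling to equal coding totals. Several glycolytic genes had some of the greatest falls, but the split of the glycolysis and fermentation list did not pass its test. Adhesin-like cell wall proteins were higher, with a median at percentile 99.6 of random lists matched on mean FPKM. That list no longer passed its test once the median rise of genes low in planktonic cells was taken off. In the authors' deposited table, 2550 of the 4674 tested loci were called at q under 0.05, of which 1237 were higher and 1313 lower in biofilm. At least 2-fold differences were found for 808 of the higher and 920 of the lower loci. At least 8-fold differences with FPKM above 0 in both modes were found for 118 higher and 183 lower loci. Many q-values were tied at 0.000133 in the authors' deposited table, the value of 1751 loci and the lowest there. Of the called loci, 2089 held a single gene on its annotated strand, 968 higher and 1121 lower, and the gene groups below were counted among these. The median log2 change over all loci with FPKM above 0 in both modes was -0.02. The summed FPKM of single coding genes was lower in biofilm by 1.04 on the log2 scale (961028 planktonic, 468548 biofilm), so scaling to equal coding totals would give 1654 higher and 896 lower called loci in place of 1237 and 1313.

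**Figure D1:**
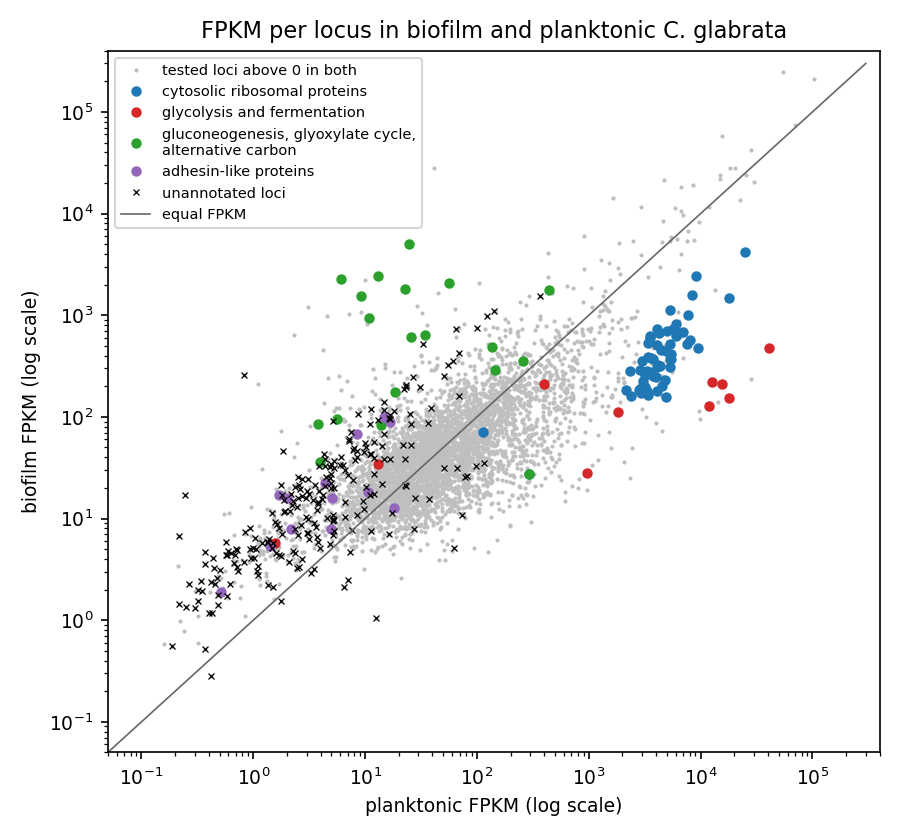
Biofilm FPKM against planktonic FPKM for each tested locus above 0 in both modes, both axes on log scales, with 1 point per locus from the authors' pooled values and a line of equal FPKM. Of the marked groups, all 58 called cytosolic ribosomal protein genes lie below the line (1 of them would lie above it after scaling to equal coding totals), and 18 of 19 called genes of gluconeogenesis, the glyoxylate cycle and alternative carbon use lie above it. Crosses mark loci with no annotated gene.

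Genes that make glucose or use 2-carbon and other non-sugar substrates had the largest median rise among the lists, 18.3-fold. PCK1 (CAGL0H06633g), phosphoenolpyruvate carboxykinase of gluconeogenesis, rose from 6.08 FPKM in planktonic cells to 2258 FPKM in biofilm, a 372-fold difference, the largest among the named called genes. The gene lies on chromosome H from 659326 to 660960 in the coordinates of the deposited table, whose genome build is not given in the sources used here. ACS1, an acetyl-CoA synthetase, rose 204-fold to 5041 FPKM. YAT1 and YAT2, carnitine acetyltransferases, rose 187-fold and 166-fold. FBP1, fructose-1,6-bisphosphatase, rose 86.3-fold, and MLS1, malate synthase of the glyoxylate cycle, rose 79.8-fold. Isocitrate lyase ICL1 rose from 56.0 to 2056 FPKM, and the regulators CAT8 and SIP4 rose from 3.91 to 35.8 and from 5.64 to 95.9 FPKM. Of 19 called genes on this list, 18 were higher, and the exception was the pyruvate carboxylase PYC2 (293 to 27.7 FPKM). This share exceeded that among the other called genes by Fisher's exact test (two-sided, adjusted p = 0.000111), and the list's median lay at percentile 100 of 10000 random lists matched on mean FPKM.

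Fatty acid oxidation and peroxisome genes followed the same direction in 16 of 17 called genes (Fisher's exact test, adjusted p = 0.000291). The β-oxidation enzymes FAA2, FOX2 and POT1 rose 13.3-fold, 12.7-fold and 9.69-fold, and the fatty acid oxidase POX1 rose 8.57-fold with q = 0.0476 in the authors' deposited table. PEX27 was the one member with the opposite change, from 15.6 to 10.7 FPKM, a direction that reverses under equal coding totals. In the tricarboxylic acid cycle list, 6 of 9 called genes were higher, including CIT3 (12.7-fold), CIT1 (3.82-fold), FUM1 (3.70-fold) and ACO1 (3.03-fold). The exact test did not separate the list from other genes (adjusted p = 0.408). The called genes that the deposited annotation places in the cycle, a different set, were higher in 11 of 12 (exact test, adjusted p = 0.00297 over 140 gene ontology terms), so the outcome depended on which genes were counted.

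Glycolytic and fermentative transcripts showed the reverse. ADH1 (CAGL0I07843g), alcohol dehydrogenase, fell 118-fold from 17953 to 153 FPKM. PGK1, phosphoglycerate kinase, fell 92.9-fold, and TDH3, glyceraldehyde-3-phosphate dehydrogenase and the most abundant member in planktonic cells at 40548 FPKM, fell 86.1-fold to 471 FPKM. FBA1, PDC1 and PFK1 fell 73.9-fold, 57.7-fold and 34.0-fold. Of 10 called genes, 8 were lower, and the list's median change of -5.47 on the log2 scale lay at percentile 0 of the matched random lists. The exact test of the split itself, which ignores size, gave adjusted p = 0.179, since PDC6 and one of a pair of genes named GLK1 were higher at low levels (13.0 to 34.3 FPKM and 1.56 to 5.79 FPKM). Among 6 called genes of the hexose transporter list, HXT4 fell from 1582 to 49.5 FPKM. The genes named HXT6/7 and HXT4/6/7 fell 20.9-fold and 11.1-fold, and RGT2 fell 4.18-fold with q = 0.0454 in the authors' deposited table. HXT3 and HXT14 were higher (66.2 to 153 FPKM and 11.1 to 34.1 FPKM). The split did not differ from other genes (exact test, adjusted p = 0.747). How the authors divided reads among close copies of these genes is not given in the sources used here.

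**Figure D2:**
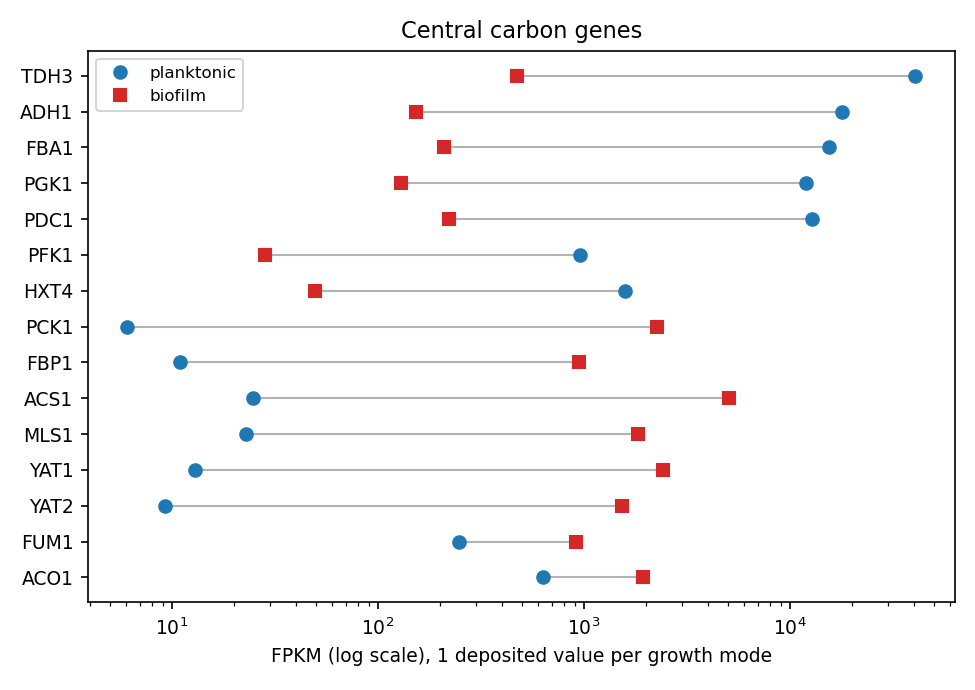
FPKM on a log axis for 15 genes of central carbon metabolism, with circles for planktonic and squares for biofilm, 1 pooled value each without an error. The glycolytic, fermentative and hexose transporter genes TDH3 to HXT4 are lower in biofilm, as ADH1 at 17953 and 153 FPKM shows, and those from PCK1 to ACO1 are higher, as PCK1 at 6.08 and 2258 FPKM shows; none of the 15 changes direction under the scalings tried.

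All 58 called cytosolic ribosomal protein genes were lower (Fisher's exact test, adjusted p = 1.97e-15), with a median 11.7-fold fall, and 1 of them would be higher after scaling to equal coding totals. RPP1B, RPL43A and RPS7B fell 22.5-fold, 20.9-fold and 20.7-fold. All 58 called ribosome biogenesis genes were lower as well (exact test, adjusted p = 1.97e-15), by a median of 3.55-fold, and 15 of them would be higher under that scaling. RPA12 and RPA190, subunits of RNA polymerase I, fell 8.57-fold and 8.10-fold, and the rRNA methyltransferase NOP2 fell 8.50-fold. All 28 called mitochondrial ribosome genes were lower by a median of 2.12-fold (exact test, adjusted p = 3.18e-07), but the median lay at percentile 7.96 of random lists of equal abundance, and 11 of the 28 would be higher under equal coding totals. Ontology terms held a few higher members, 1 of 39 called genes for ribosome and 5 of 76 for nucleolus.

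Among adhesin-like proteins, the cell wall proteins by which *C. glabrata* attaches to surfaces and host cells, 12 of 13 called genes were higher in biofilm (Fisher's exact test, adjusted p = 0.00301). The list's median lay at percentile 99.6 of the random lists matched on mean FPKM. AWP13 and AWP2 rose from 14.6 to 101 FPKM and from 8.45 to 68.4 FPKM. EPA2 and EPA3 rose 10.2-fold and 8.03-fold, to 17.2 and 16.1 FPKM, and PWP5 rose from 16.6 to 88.3 FPKM. EPA6, on chromosome C from 1284 to 7725, was the exception, with 18.3 FPKM in planktonic cells and 12.8 FPKM in biofilm, a direction that reverses under equal coding totals. EPA1, EPA7 and AWP1 were not among the named called loci, and AWP7 went from 4.97 to 7.97 FPKM. Many other low transcripts were higher in biofilm. Of 144 tested genes under 3.10 FPKM in planktonic cells, 143 had a higher biofilm FPKM, with a median rise of 4.25 FPKM, although a choice by low planktonic FPKM favours rises. Of 31 genes under that level in biofilm, the reverse choice, 6 had a lower biofilm FPKM. With a rise of that size taken off every biofilm value, 9 of the 13 adhesin genes were higher and the exact test gave adjusted p = 0.162.

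The yapsins, surface aspartyl proteases, were higher in 5 of 6 called genes without separating from other genes (exact test, adjusted p = 0.172). YPS11 rose 21.9-fold to 329 FPKM and YPS1 rose 3.00-fold, while YPS3 fell from 1018 to 92.5 FPKM. YPS4 and YPS5, at 4.83 and 6.13 FPKM in biofilm, were no longer higher with 4.25 FPKM taken off. Cell wall synthesis and structure genes were mostly lower, with 16 of 20 called (Fisher's exact test, adjusted p = 0.0465) at percentile 0.32 of the matched lists and 6 rather than 4 members higher under equal coding totals. The list passed under 5 of 8 alternatives (exact test, adjusted p from 0.00590 to 0.0894). The ontology terms fungal-type cell wall (5 of 23 higher) and fungal-type cell wall organization (6 of 14 higher) did not pass (exact test, adjusted p = 0.210 and 1). FKS1, a catalytic subunit of β-1,3-glucan synthase, fell 11.0-fold, the glucanosyltransferase GAS1 fell 11.3-fold, and the wall proteins CIS3 and PIR1 fell 33.2-fold and 13.4-fold. The regulators of adhesion and biofilm split evenly, 5 higher and 5 lower (exact test, adjusted p = 1), with 8 of the 10 higher under equal coding totals. PHD1 and SOK2 rose 4.47-fold and 2.94-fold and STE12 rose from 19.6 to 31.2 FPKM, while RIF1 and SIR3, which act in subtelomeric silencing, fell from 26.3 to 9.96 FPKM and from 37.3 to 19.1 FPKM, the latter a direction that reverses under equal coding totals. YKU80, on the same list, rose 2.74-fold. YAK1 and SIR4 were not among the named called loci.

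Ergosterol genes, which include the azole target ERG11, were lower in 14 of 17 called genes (Fisher's exact test, adjusted p = 0.0484). ERG11 fell 4.87-fold, NCP1 fell 6.70-fold, and ERG4 and ERG9 fell 5.40-fold and 5.30-fold. The ontology term ergosterol biosynthetic process was higher in 1 of 14 called genes (exact test, adjusted p = 0.0489). The list's median lay at percentile 43.5 of lists of equal abundance, and 9 of the 17 would be higher under equal coding totals. The list passed under 1 of 8 alternatives, which left its own members as they were, and not with q under 0.01 or a 2-fold minimum (exact test, adjusted p from 0.0483 to 0.431). Drug efflux pumps did not separate from other genes (2 of 7 higher, or 4 of 7 under equal coding totals; exact test, adjusted p = 0.519). SNQ2 rose 2.42-fold and the pump regulator PDR1 rose 1.65-fold, while TPO2 and RSB1 fell 16.3-fold and 5.86-fold. A locus that joins 2 genes, one carrying the name of the pump gene PDH1, rose 3.93-fold and cannot be divided between them. That locus is printed in a span shared by 108 loci, with q = 0.0369 in the authors' deposited table, and was not called at q under 0.01. CDR1, AUS1 and FKS2 were not among the named called loci. In the list of hypoxia and sterol-oxygen response genes, all 3 called genes were lower (exact test, adjusted p = 0.342): HEM13 and SUT1 fell 14.8-fold and 12.6-fold, and OLE1 differed 1.45-fold, a direction that reverses under equal coding totals.

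Protein breakdown genes were higher. In the proteasome list, 17 of 18 called genes were higher (Fisher's exact test, adjusted p = 0.000176) by a median of 1.81-fold, among them RPN8, RPN11 and RPN5 (2.29-fold, 2.28-fold and 2.16-fold), and the polyubiquitin gene UBI4 rose 9.43-fold. Autophagy and vacuolar protease genes were higher in 16 of 18 (exact test, adjusted p = 0.000854), with the proteases PRB1 and PEP4 up 5.55-fold and 3.71-fold and ATG12 and ATG2 up 4.47-fold and 3.69-fold. Among ontology terms, piecemeal microautophagy of the nucleus was higher in 10 of 11 (exact test, adjusted p = 0.00543). Macroautophagy (8 of 15), mitophagy (8 of 11) and pexophagy (7 of 10) did not pass (exact test, adjusted p = 0.494, 0.117 and 0.234). Of 15 called nutrient permeases, 10 were higher (exact test, adjusted p = 0.179). PUT4, a proline permease, and GAP1, the general amino acid permease, rose 119-fold and 78.9-fold, and AGP2 and DIP5 rose 10.9-fold and 10.7-fold. Amino acid synthesis genes were lower in 28 of 40 (exact test, adjusted p = 0.0686), although 20 of the 40 would be higher under equal coding totals. The lower genes included CYS3 (15.8-fold), GLY1 (10.3-fold) and SHM1 (9.90-fold).

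DNA replication genes were lower in 20 of 24 called genes (Fisher's exact test, adjusted p = 0.00895), although 12 of the 24 would be higher under equal coding totals. The list passed under 5 of 8 alternatives and not with a 2-fold minimum, loci alone in their span or equal coding totals (exact test, adjusted p = 0.134, 0.104 and 0.268). With a 2-fold minimum 3 of 16 members were higher, and with loci alone in their span 4 of 17, so fewer genes entered those tests. The ontology terms DNA replication initiation (3 of 13 higher) and DNA replication origin binding (1 of 11 higher) did not pass (exact test, adjusted p = 0.439 and 0.156). RNR4 and RNR1, subunits of ribonucleotide reductase, fell 50.4-fold and 14.2-fold, and the sliding clamp POL30 fell 18.2-fold. Only 2 histone genes were called, both lower (HTB1 from 594 to 222 FPKM, HTA1 from 58.6 to 20.1 FPKM), too few to test. Of the called cyclin and mitosis genes, 10 of 15 were higher (exact test, adjusted p = 0.179). DBF2, of the mitotic exit network, rose 5.06-fold, while the mitotic cyclin CLB2 fell from 49.2 to 5.96 FPKM. Sporulation and mating genes were higher in 13 of 14 (exact test, adjusted p = 0.00171), from low levels: SPO11 from 1.16 to 6.41 FPKM, AGA1 from 2.87 to 11.8 FPKM and FAR1 from 6.65 to 27.7 FPKM. The median of this list lay at percentile 99.1 of the random lists matched on mean FPKM. With 4.25 FPKM taken off the biofilm values, 10 of the 14 were higher and the exact test gave adjusted p = 0.106. Under equal coding totals 13 of the 14 were higher and the exact test gave adjusted p = 0.0679. The ontology term ascospore formation ran the other way, with 3 of 12 called genes higher and a median log2 change of -0.97, smaller in size than the 1.04 shift of equal coding totals, and did not pass (exact test, adjusted p = 0.567).

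Heat shock proteins and chaperones were lower in 10 of 11 called genes (Fisher's exact test, adjusted p = 0.0340), with SSE2, MGE1 and HSP60 down 6.89-fold, 4.72-fold and 3.95-fold, and 5 of the 11 would be higher under equal coding totals. Nuclear genes of the respiratory chain and ATP synthase were lower in 12 of 14 (exact test, adjusted p = 0.0358), with ATP2 and TIM11 down 3.38-fold and 3.36-fold, but their median lay at percentile 82.4 of equally abundant genes and 5 of the 14 would be higher under that scaling. The heat shock list lay at percentile 72.7. In the reference, 35 genes carry a symbol of that list, and members that were not called could not be counted. Of 8 alternatives, the respiratory list passed under 1 (exact test, adjusted p from 0.0379 to 0.132), which left its own members as they were, and not with q under 0.01 or a 2-fold minimum. The heat shock list passed under 2 (exact test, adjusted p from 0.0111 to 0.338). It did not pass with a 2-fold minimum, where 0 of 6 remaining members were higher. In oxidative stress defence, 5 of 15 called genes were higher, or 9 under equal coding totals (exact test, adjusted p = 0.519). The peroxiredoxins TSA1 and AHP1 fell 8.11-fold and 5.05-fold, and SOD1 differed 1.98-fold, a direction that reverses under equal coding totals. CTA1 and SOD2 were not among the named called loci. Trehalose and glycogen genes were lower in 5 of 7, or 3 of 7 under equal coding totals (exact test, adjusted p = 0.519), with GLG1 and GSY1 down 4.98-fold and 4.32-fold and the glucoamylase gene SGA1 up from 5.47 to 123 FPKM. Of 8 called iron and copper genes, 4 were higher and 4 lower, with 5 higher under equal coding totals (exact test, adjusted p = 1), and ARN1 and ATX1 rose 2.27-fold and 2.12-fold, while ISA1, MRS4 and CTR1 fell 4.72-fold, 2.59-fold and 2.38-fold. Genes of the mitochondrial genome could not be assessed, since only nuclear locus tags were counted and the reference holds 0 genes with a listed symbol.

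**Figure D3:**
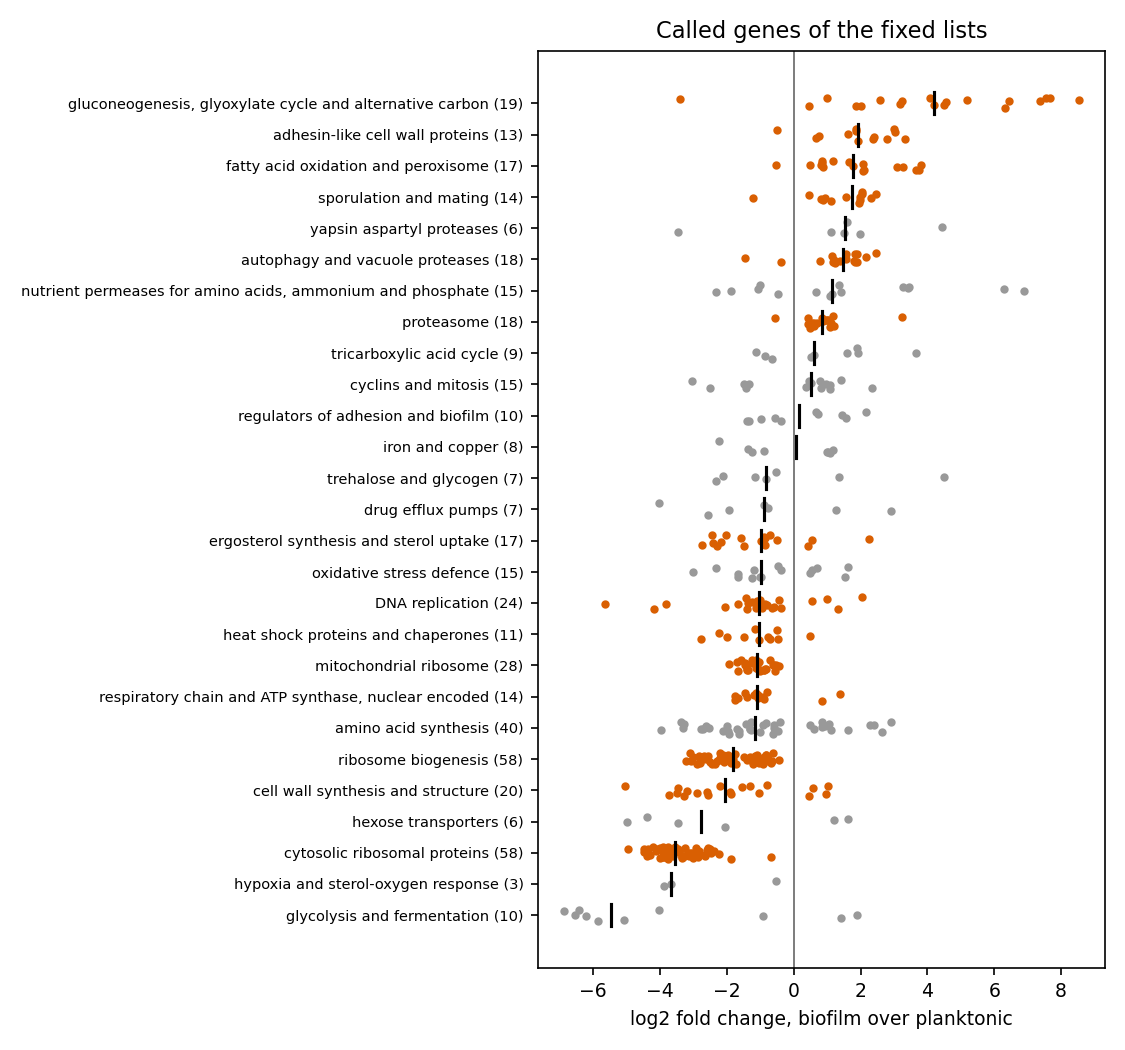
Log2 fold change, biofilm over planktonic, of each called gene in the 27 lists with at least 3 called genes, with the number of genes in brackets and a bar at each median. Orange lists passed Fisher's exact test of their higher and lower split at adjusted p under 0.05, which 6 lists did towards higher and 8 towards lower, and grey lists did not. A shift of every point by 1.04 to the right would show scaling to equal coding totals, under which 9 lists pass. The iron and copper list then has 62.5% of its genes higher, just below the 64.5% of all called genes.

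Among the remaining genes with the greatest changes, FMP16 and SPG1 rose 221-fold and 215-fold, the transcriptional repressor XBP1 rose 189-fold, and GRE1 rose 144-fold. At the other end, PMA1, the plasma membrane proton pump, fell 62.8-fold from 4526 to 72.1 FPKM, and SEC53 and MPG1, enzymes of mannose nucleotide supply, fell 40.7-fold and 33.8-fold. MPG1 is printed in a span shared by 37 loci, with q = 0.0252 in the authors' deposited table, and was not called at q under 0.01. Of the 123 genes named by rule, 27 lie in such shared spans, PMA1, ADH1, PGK1, ACS1 and FBP1 among them.

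The 51 loci of small nuclear and nucleolar RNA, U3 and the signal recognition particle RNA made up 27.4% of the summed planktonic FPKM and 57.1% of the summed biofilm FPKM. FPKM is scaled to transcript length, so these are not shares of reads. Over the 45 of these loci above 0 in both modes, the median log2 change was 0.31. The signal recognition particle RNA rose 4.55-fold to 246949 FPKM and U3 rose 2.06-fold to 212024 FPKM. Of the 51 loci, 12 were called higher and 6 lower in the authors' deposited table.

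The median change differed between the least and the most abundant genes. Among coding genes split into 10 bins by geometric mean FPKM, the median log2 change was 0.91 in the lowest bin and -1.06 in the highest, while bins 2 to 7 had medians between -0.09 and 0.14 without an order. Under equal coding totals these 2 medians would be 1.94 and -0.02. Without the ribosome and glycolysis lists the median of the highest bin was -0.73, and it would turn to 0.31 under equal coding totals. In the lowest bin 162 genes were called higher and 26 lower, and in the highest bin 64 were called higher and 218 lower, or 179 and 9, and 104 and 178, under equal coding totals.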

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

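The tests of low abundance in this part were chosen after the result was seen. Loci with no annotated gene lie outside the gene comparison, and 167 of them were called higher in biofilm against 6 lower, that is 96.5% (exact 95% interval 92.6 to 98.7%). Their median FPKM was 3.10 in planktonic cells and 15.4 in biofilm. Low abundance alone would give the share among called genes in 5 bins of like mean FPKM. That share was 73.9% (bootstrap interval 71.9 to 75.8%), below the interval of the unannotated loci. Without bins of under 20 genes, the thinnest of which held 17, it was 67.2%. The bins took in 1980 of the 2089 called genes, so abundance was matched only loosely. Ends of neighbouring genes that rose were set in advance to need at least 80% of neighbours higher. Of 78 nearest annotated loci within 1000 bases, 53.8% were (exact interval 42.2 to 65.2%), against 50.2% of all such loci. Genomic DNA in the biofilm libraries is a candidate explanation. The share of 3852 tested genes under 5.32 FPKM, a level set from the median rise of these loci (10.6 FPKM), was 2.39% in biofilm. It was 5.61% in planktonic cells, so a low share decides nothing. Genes near 0 in planktonic cells had a median rise of 4.25 FPKM (bootstrap interval 3.72 to 5.30), below that level, although these were chosen by a low planktonic FPKM, which favours rises, and the called loci by a significant change. Over all 260 tested unannotated loci, called or not, the median rise was 6.94 FPKM. A level set in the same way from that rise would lie below 3.72, so the outcome depends on the choice of called loci. An even floor as large as 10.6 FPKM is argued against, and a smaller one stays open. Transcription specific to biofilm was not tested and stays open too.

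Antisense-class loci, which lie opposite an annotated gene, were called in 37 cases, 16 higher and 21 lower. Of the 28 with a single-gene partner, 78.6% changed in the direction of that gene (exact interval 59.0 to 91.7%; exact binomial p = 0.00372 against an even split). RNR4 is the partner of more than 1 locus, so the pairs are not all independent. Reads of the gene counted on both strands would give at least 80%, which the interval includes. Antisense transcripts that change with their gene would give the same, so the share cannot tell these apart without the strand setting. In some pairs the antisense-class locus had far more planktonic FPKM than its gene, as for CAGL0H01595g (905 against 25.3) and CAGL0L12848g (522 against 30.9). For such pairs this argues against reads of the gene counted on both strands as the only source. In most pairs the gene had the greater planktonic FPKM, and there the question stays open. PMA1, chosen with MEU1 after the values were seen, had 4526 and 72.1 FPKM on the gene and 2340 and 24.9 FPKM on the antisense-class locus. MEU1 goes the other way, falling from 123 to 37.5 FPKM while its antisense-class locus went from 0.608 to 11.4 FPKM.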

How the results depend on the processing

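The alternatives on subsets of loci, unsplit names, scalings and constants were chosen after seeing the data; the others were planned. No paired analysis was possible because the files hold 1 pooled value per growth mode. For the same reason other normalizations, count models, leaving out replicates, other splits of the samples, a replicate block, and camera or fry were not run. Depth is unknown. Counts of called loci stayed within 1.5 times, except that a 2-fold minimum left 808 higher loci and loci alone in their printed span gave 875 lower, both because fewer loci qualify. Scaling to equal coding totals moved the higher share of called loci from 48.5% to 64.9% without retesting. Of 27 lists, 14 passed. With q under 0.01, 12 passed, with a 2-fold minimum 10, with several-gene loci included 10, 9 with loci alone in their span, 9 with equal coding totals, 8 with 6.94 FPKM (the median rise of 260 tested unannotated loci) taken off biofilm, and 9 with 4.25 FPKM taken off. Past the threshold under every alternative were 7 of the 14: gluconeogenesis, fatty acid oxidation, autophagy, proteasome and the 3 ribosome lists. A stricter call or a subset of loci leaves fewer genes in a list, so a list can drop out there without a changed split. By Fisher's exact test adhesins had adjusted p = 0.259 and 0.162 with the constants taken off (range over 8 alternatives 0.000324 to 0.259). The cause was not tested. By the same exact test the iron and copper list turned direction against other genes with q under 0.01, loci alone in their span and equal coding totals (adjusted p = 1 each); hexose transporters turned without splitting names (adjusted p = 1), and sporulation and mating turned with 6.94 FPKM taken off (adjusted p = 1). Of 123 named genes, both pseudocounts reversed none. Equal coding totals reversed EPA6 (0.53), SOD1 (0.047), OLE1 (0.50), TPS1 (0.21) and YCF1 (0.16), as log2 changes. Taking off 6.94 FPKM reversed AWP7 (-1.55), SPO11 (-1.11), YPS4 (-1.15) and YPS5 (-1.66), and taking off 4.25 FPKM reversed AWP7 (-0.34), YPS4 (-0.50) and YPS5 (-0.14). A q-value under 0.01 lost 6 of the 123 (ARN1, EPA6, MPG1, OLE1, RGT2 and the locus holding PDH1) and a 2-fold minimum 8. POX1, YKU80 and PEX27, named outside the rule, were also lost at q under 0.01.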

Other observations

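Apart from CIT3, which the naming rule also gave, the genes named in this part were chosen after the values were seen. So were the tests of gene ontology terms. A run of 5 adjacent genes named as β-mannosyltransferases, enzymes that add mannose to cell wall glycans, on chromosome B from 279334 to 293137 was higher in biofilm in all 5 members. BMT3 and BMT2 rose 26.1-fold and 21.3-fold, from 1.18 to 31.0 FPKM and from 5.80 to 123 FPKM, BMT6 and BMT4 rose 9.61-fold and 6.35-fold, and the BMT5 of this run rose 2.72-fold. All 5 were still above their planktonic value with 6.94 FPKM taken off. A gene of the same name on chromosome G fell 2.86-fold. Further genes, not tested as a group, were CIT3, ICL2 and CAGL0L09108g. CIT3, a member of the tricarboxylic acid cycle list above, rose 12.7-fold. Its neighbour CAGL0L09108g, annotated with 2-methylcitrate dehydratase activity, rose 32.9-fold from 6.86 to 226 FPKM, and ICL2 rose 22.6-fold.

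Of 140 gene ontology terms tested by Fisher's exact test, 33 passed at adjusted p under 0.05, 11 towards higher and 22 towards lower. Beside the groups above, genes placed in the fungal-type vacuole membrane were higher in 31 of 36 (exact test, adjusted p = 7.95e-07), genes with ubiquitin-protein transferase activity in 14 of 16 (adjusted p = 0.00117) and integral membrane genes in 192 of 348 (adjusted p = 1.04e-07). Genes of the cytoplasmic stress granule were higher in only 4 of 31 (exact test, adjusted p = 0.00544).

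Some large differences were not called. CAGL0J04202g had 41.1 FPKM in planktonic cells and 27875 FPKM in biofilm with q = 0.240 in the authors' deposited table, in a span shared by 5 loci. Among 901 tested loci with at least a 4-fold difference, 67.6% were called where the span was shared and 98.6% where it was not (Fisher's exact test, p = 2.92e-42), which is consistent with reads shared within a span widening the authors' error. Low abundance was not decided: the 139 uncalled loci had a median mean FPKM of 60.0, between the lower quartile (31.4) and the median (106) of the 762 called ones.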
